A study of Mus musculus with 3 samples.

How the data were processed

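Total RNA-seq libraries of 3 T-helper 1 samples were analysed, 1 group with 3 biological replicates numbered as in the labels' descriptions. The labels name total RNA as the molecule and as the assay, while the library protocol they point to is named for poly(A) RNA. The file headers carry a 16 hr tag that the labels do not state. The deposited values are whole-number counts per gene, made per the file headers with featureCounts v1.4.6-p4 on paired reads with strand setting 1, over exons of GENCODE vM13 on mm10. The aligned file names in the headers contain the words star2 and stranded; the aligner's version and the kit are not given in the sources used here. The length of each gene, in bases, was deposited beside its count per the file headers.

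The design had assumed estimated counts and TPM from another tool. Counts were found instead, so TPM and FPKM were computed here from the deposited counts and gene lengths, and tests of counts used the counts without rounding. Of 50600 gene identifiers 50376 were named from GENCODE vM21, and 490 of 492 list genes were found. Overlaps between strands were computed from the exon coordinates in the deposited tables. Clear genes, 15865 of 21764 coding genes, have no exon within the body of an opposite-strand gene.

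The following were fixed before the data were examined: the 32 gene lists, the tests, the alternatives not stated to be later, and the rule for the genes named. The rule takes 15 regulators, cytokines and co-receptors, the 4 highest members of each list with up to 4 undetected ones, the 15 highest coding genes outside the mitochondrial genome, the 10 coding genes of largest SD, and the 5 highest cytokine, cytokine receptor, chemokine receptor and transcription factor genes. Other genes are said to be chosen later where they appear. The result of 1 gene of the rule is not reported here. A gene was called detected at a TPM of at least 1 in every library and not detected under 1 in every library. Log values use a pseudocount of 1.

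Lists were compared with two-sided permutation tests across genes (100000 resamples, Benjamini-Hochberg over 4 helper lists and over 9 lists of other cell types, genes on both lists left out). List percentiles came from 10000 random lists, matched on expression in 20 bins for the spread. The edgeR common dispersion used TMM scaling and filterByExpr with an intercept alone. A count of 0 was taken to allow 3 counts, and ratio intervals are exact at 95%. Alternatives were other pseudocounts, units, filters, scalings and statistics, and each replicate left out; clear genes, and clear genes at 5 kb from any opposite gene, were added after the data were seen, as were the overlap shares and nested pairs (at least 500 bases, 90% inside, 30 counts in all). No comparison between conditions was possible with 1 group.

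On simulated lists of the Th1 and Th2 sizes (27 and 20 genes, 2000 simulations) the permutation test gave p under 0.05 in 5.55% with no shift and in 81.25% with a log2 shift of 2. The simulated p was not adjusted. Lists of clear members were smaller, with 22 Th1 genes against 12 Th2, 12 Th17, 10 Treg and 9 Tfh genes. The 81.25% therefore does not carry over to the adjusted comparisons over clear members. On simulated counts, set coefficients of variation of 0.1, 0.3 and 0.6 were estimated at 0.0991, 0.295 and 0.556, and all 200 genes raised 8-fold in 1 library among 5254 had an SD above 1, as did 1 of 5054 unchanged genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.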

Results

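RNA was sequenced from mouse T-helper 1 cells, the CD4 T cell subset defined by the regulator Tbx21 (T-bet) and the cytokine Ifng. The cells were primary cells of strain C57BL/6NJ, in 1 group of 3 biological replicates with separate biosample records and a shared donor record. There was no second condition, so genes and gene lists were compared within each library and values were set against the spread between the 3 libraries. The deposited gene counts summed to 4764598 in replicate 1, 2568928 in replicate 2 and 2815439 in replicate 3. A TPM of 1 stood for 2.25, 1.28 and 1.59 counts per kilobase in replicates 1, 2 and 3. Counting intervals and floors below cover counting error only.

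Many of the highest counts lay on genes that overlap a gene of the other strand, which bears on every level that follows. Phykpl, a lysine metabolism enzyme, held 46509, 31946 and 39198 counts in replicates 1, 2 and 3, while Hnrnpab, an RNA-binding protein gene whose exons overlap it by 809 bases on the other strand, held 6041, 2392 and 2830. Gm20721, opposite the G protein gene Gnas, held 25079, 15531 and 23749 counts against 1090, 652 and 469 for Gnas. The mitochondrial gene mt-Nd6, encoded on the strand opposite to the other mitochondrial mRNAs, had 6.40, 10.3 and 24.5 times the counts per kilobase of mt-Co1 in replicates 1, 2 and 3. Phykpl and Gm20721 are among the highest coding genes under the naming rule; Hnrnpab, Gnas, mt-Nd6 and mt-Co1 were chosen after their values were seen. Genes with exons overlapped by opposite-strand exons, 8189 of 50600 (16.2%), held 56.1%, 60.3% and 71.6% of the counts. Among 90 noncoding genes lying at least 90% inside the exons of an opposite coding gene, 75, 75 and 79 had more counts per kilobase than that coding gene, and 72 did so in all 3 libraries. The median ratio of coding to noncoding counts per kilobase was 3.83% ± 1.54 (SD, n = 3). For this reason, values are also given for clear genes, whose exons meet no gene of the opposite strand, with TPM recomputed over those genes alone. This setting was chosen after the data were seen. Clear genes held 25.8% ± 6.94 of TPM (SD, n = 3), so their recomputed values lie on a larger scale. The setting removes overlap, but it does not guard against counting on the opposite strand. In that case the counts of clear genes may be a small remainder of reads.

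**Figure D1:**
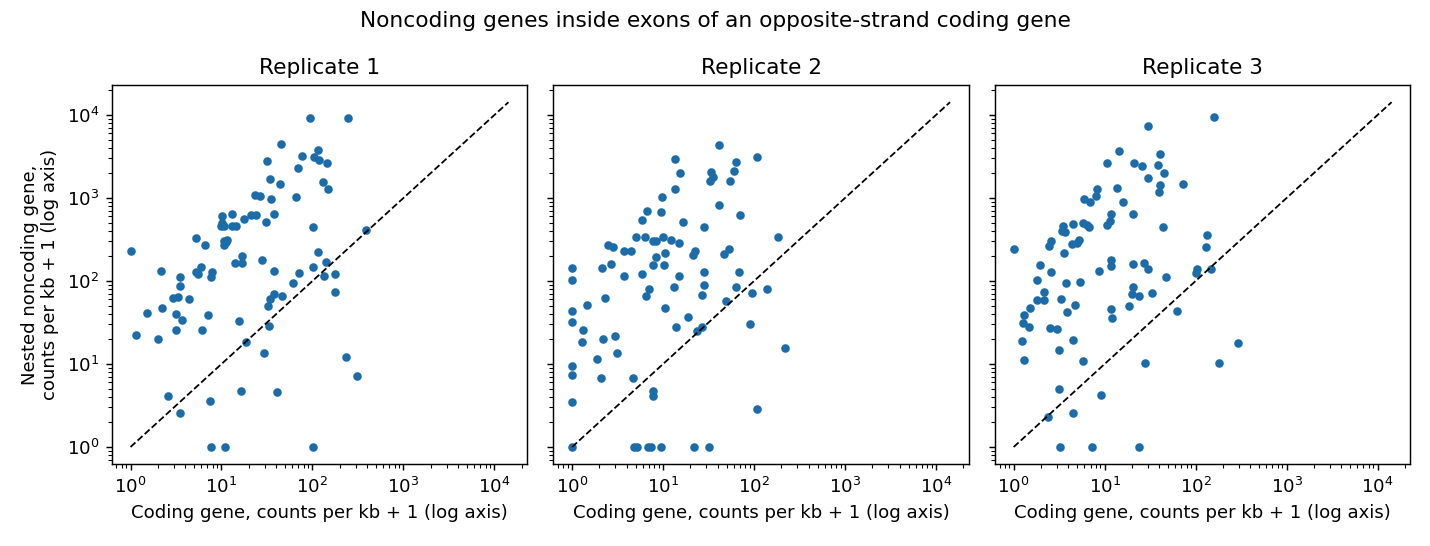
Counts per kilobase plus 1 of 90 nested noncoding genes (vertical log axis) against those of the opposite-strand coding gene around each (horizontal log axis), 1 point per pair and 1 panel per library. The dashed line marks equal values; 75, 75 and 79 of the pairs have the higher value in the noncoding gene in replicates 1, 2 and 3.

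Of the 15 most abundant coding genes outside the mitochondrial genome, Hsp90ab1, a cytosolic chaperone (4211 TPM ± 1099; SD, n = 3), Eef1a1, a translation elongation factor (3964 ± 1375), Npm1, a nucleolar protein (3203 ± 1049), and the ribosomal protein genes Rpl36, Rps24, Rps15 and Rpl4 were clear genes. Rpl36 had 3327 TPM ± 355 and Rps24 had 3272 ± 846. Gm20721 (8588 TPM ± 1327), Gm17606, Rpl32, G530012D18Rik, Mettl23, Tlcd1, Acat3 and Phykpl overlapped opposite-strand exons. In all 3 libraries 8668 coding genes reached a TPM of 1, with 10102, 9326 and 9639 in replicates 1, 2 and 3. These numbers include genes that overlap opposite-strand exons. Of the 15865 clear coding genes, 5932 reached 1 in all 3 libraries in recomputed TPM, where that cutoff is looser. Part of the SD of a gene in TPM is a shift shared by the library. Over 9932 coding genes with a mean TPM of at least 1, the median deviation from the gene's mean log2(TPM + 1) was 0.32, 0.11 and -0.41 in replicates 1, 2 and 3. Over clear genes it was 0.10, -0.02 and -0.05.

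T cell genes were expressed and markers of most other cell types were near 0. All 22 T cell genes were detected, with a median of 91.1 TPM (clear members, 403 TPM). Trac, the T cell receptor alpha constant gene, had 339 TPM ± 123 (SD, n = 3), Trbc2 had 244 ± 104, the surface receptor Cd5 had 209 ± 72.0, and Cd4, the co-receptor of helper cells on chromosome 6 from 124864692 to 124888221 (mm10), had 186 ± 60.3. Cd8a had 0 counts in each library, which by counting error alone allows up to 0.647 TPM, whereas Cd8b1 had 17.4 TPM ± 10.7. Counts of 0 were not limited to such markers: mt-Co2, mt-Co3 and mt-Atp6, respiratory genes that all cells use, also had 0 counts in each library. They lie in an unbroken stretch of mitochondrial genes at 0 counts, from mt-Td to mt-Nd4l. On either side of it, mt-Co1 had 8179, 4091 and 2341 counts and mt-Nd4 had 1721, 977 and 1047 in replicates 1, 2 and 3. These mitochondrial genes were chosen after their values were seen. Whether their zeros share a cause with that of Cd8a was not tested. The detected members were 1 of 13 for B cells, 3 of 14 for macrophages and monocytes, 1 of 13 for dendritic cells, 0 of 12 for neutrophils, 0 of 13 for NK cells, 2 of 11 for CD8 and gamma delta T cells, 1 of 10 for erythroid cells, 0 of 11 for mast cells and basophils, and 1 of 13 for stromal, endothelial and epithelial cells. The highest of these markers were Ighm, an immunoglobulin heavy chain gene (78.5 TPM ± 25.9), and the growth factor receptor Csf1r (124 ± 12.7), which overlaps opposite-strand exons of Hmgxb3 by 871 bases.

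The mean log2(TPM + 1) of the T cell list exceeded that of each of the 9 other lists in 3 of 3 libraries. The differences ranged from 5.51 ± 0.48 to 6.33 ± 0.42 (SD, n = 3) with all members and from 7.08 ± 0.38 to 8.53 ± 0.08 with clear members, and the list with the smallest difference was not the same in both. The two-sided permutation test across genes gave p = 1e-05 and a Benjamini-Hochberg adjusted p = 1e-05 for all 9, the smallest value that 100000 resamples can give, with all members and with clear members. Genes are not independent replicates, so the test describes these lists in these libraries.

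**Figure D2:**
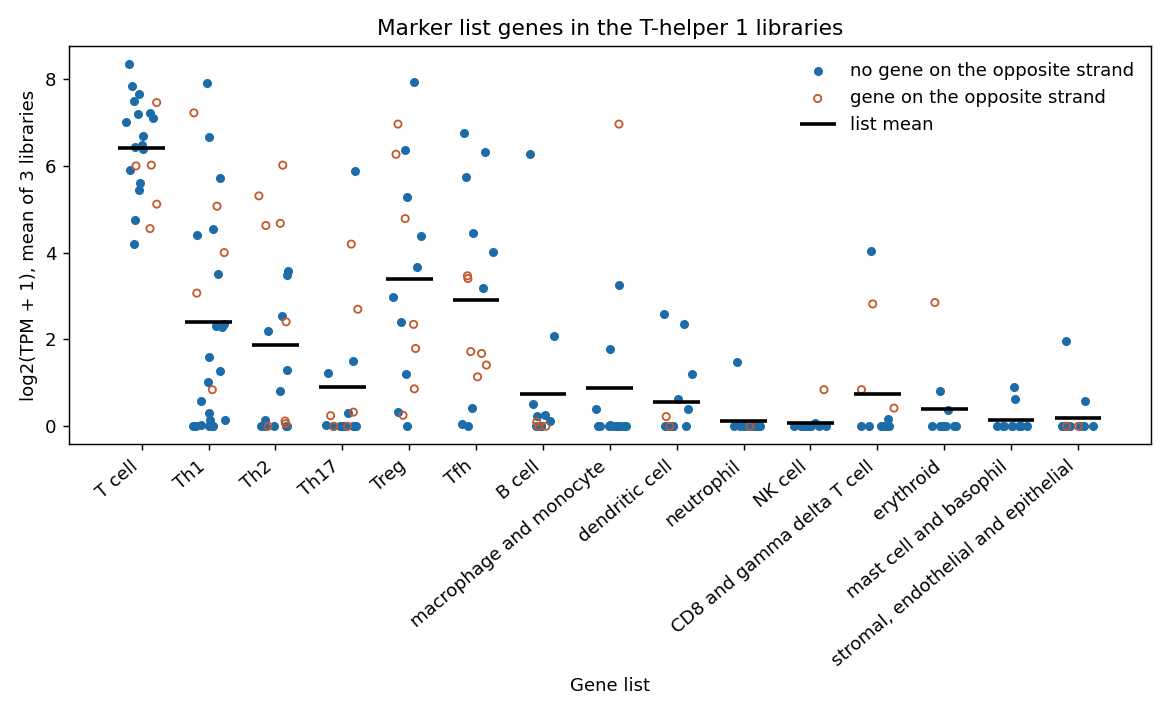
Each point is 1 gene of a marker list, placed at its log2(TPM + 1) averaged over the 3 libraries (vertical axis); lists are on the horizontal axis and bars are list means. Filled points are clear genes; the mean of the T cell list lies above the means of all 9 lists of other cell types, although single markers such as Csf1r and Ighm lie among the T cell genes, and the Th1 mean lies between those of the other helper lists.

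Of the 27 genes of the Th1 list, 12 were detected and 10 were not. The detected ones were led by Lta, lymphotoxin alpha (244 TPM ± 70.6; SD, n = 3), Il2, a T cell growth factor with an opposite gene (173 ± 99.0), Tnf (109 ± 55.8) and the chemokine Ccl4 (59.7 ± 33.6). The chemokine receptor Cxcr3, the chemokine Ccl5, the granule protein gene Nkg7 and Ifng were under 1 TPM in every library. Among the other helper lists, 9 of 20 Th2, 4 of 18 Th17, 13 of 17 Treg and 11 of 15 Tfh genes were detected. The Treg list was led by the costimulatory receptor Tnfrsf4 (257 TPM ± 96.5), Foxp3 and Il2ra (83.6 ± 23.7), the Tfh list by Cd200 (116 ± 52.6), Btla (88.5 ± 43.9) and Pdcd1 (56.0 ± 23.6), the Th17 list by Batf (63.9 ± 31.1), and the Th2 list by Stat6 (65.3 ± 19.5), which overlaps opposite-strand exons of Nab2 by 40 bases.

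The Th1 list did not differ detectably from any of the 4 helper lists in mean log2(TPM + 1). The difference was 0.54 ± 0.17 against Th2 (adjusted p = 0.516), 1.49 ± 0.21 against Th17 (p = 0.0303, adjusted p = 0.121), -0.99 ± 0.16 against Treg (adjusted p = 0.415) and -0.51 ± 0.31 against Tfh (adjusted p = 0.516), by the two-sided permutation test across genes. Each difference had the same sign in 3 of 3 libraries. Over clear members the differences were 1.04 ± 0.15, 1.84 ± 0.13, -1.96 ± 0.34 and -1.76 ± 0.59 in the same order, with an adjusted p of 0.320, 0.226, 0.226 and 0.237 in the same permutation test, within a range of 0.0903 to 0.734 over all alternatives. With members at 1 TPM in any library, the Tfh difference turned to 0.39, also short of the threshold.

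Tbx21, the Th1 regulator on chromosome 11 from 97098071 to 97115331 (mm10), had 2, 10 and 2 counts in replicates 1, 2 and 3, or 1.34 TPM ± 1.57 (SD, n = 3). Gata3, the Th2 regulator, had 43, 23 and 23 counts, Bcl6, the Tfh regulator, had 21, 23 and 12, and Foxp3, the Treg regulator, had 1001, 536 and 1010. Foxp3 overlaps opposite-strand exons of Ccdc22 by 590 bases, and Gata3 and Bcl6 also overlap opposite-strand exons, whereas Tbx21 is clear. Ccdc22, chosen after its values were seen, had 36, 23 and 52 counts, below Foxp3 in each library as in the pairs described above. If reads were counted on the opposite strand, the Foxp3 counts may not be reads of Foxp3. The log2 ratio of Tbx21 to Gata3 was -2.37 ± 1.66, to Foxp3 -7.22 ± 1.86 and to Bcl6 -0.96 ± 1.11 (SD, n = 3). The ratios to Gata3 and Foxp3 were below 0 in 3 of 3 libraries, with an exact sign-flip p = 0.25 for each, the smallest that n = 3 allows. In replicate 2, which held 10 of the 14 Tbx21 counts, the ratios to Gata3, Foxp3 and Bcl6 were -0.52, -5.06 and 0.23. These ratios set a clear gene against overlapped ones.

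Signature cytokines other than Il4 and Il21, which had 6 counts or more in each library, were close to the floor of the measurement. Ifng, on chromosome 10 from 118441046 to 118445892 (mm10), had 1, 0 and 0 counts; by counting error alone, a count of 0 allows up to 1.82 TPM. Il13, Il17a, Il17f and Il10 had 0 counts in each library and Il5 had 1, 0 and 0. Il4 had 7, 14 and 9 counts (5.36 TPM ± 3.27; SD, n = 3) and Il21 had 12, 14 and 6. Over the 3 libraries the length-scaled ratio of Ifng to Il4 was 0.0316, with an exact 95% counting interval of 0.000774 to 0.190, and that of Ifng to Il21, which has opposite-strand exons, was 0.127 (0.00312 to 0.760). In replicate 1, the library with an Ifng count, the log2 ratio was -2.89 to Il4 and -1.56 to Il21. With a floor of 3 counts in place of 0, the upper bounds in replicates 2 and 3 were -2.30 and -1.66 to Il4, and -0.20 and 1.02 to Il21. No ratio is given for the others, which were at or under that floor together with Ifng.

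Genes of activated T cells were expressed. Of 20 activation genes, 17 were detected (median 30.3 TPM; clear members, 102 TPM), led by Tnfrsf4, the transcription factors Irf4 (232 TPM ± 77.3; SD, n = 3) and Myc (204 ± 46.2), and Cd40lg, the ligand for B cell help (183 ± 83.1). Of 16 naive and memory genes, 13 were detected, led by Tcf7, which has an opposite gene (193 ± 44.2), and the lymph node homing receptor Ccr7 (190 ± 62.8). Of 13 inhibitory receptor genes, 9 were detected, led by Btla, Pdcd1, Lag3 (51.8 ± 22.7) and Cd274. Of 16 cytotoxic genes, 3 were detected. Of 34 interferon response genes, 15 were detected and 13 were not, and Bst2 was the highest (63.7 ± 13.7).

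All 19 glycolysis genes and all 22 oxidative phosphorylation genes were detected, with medians of 57.7 and 71.1 TPM. Ldha, lactate dehydrogenase A, had 511 TPM ± 213 and Pkm 333 ± 107, and Atp5b, an ATP synthase subunit, had 366 ± 146 (SD, n = 3). Of 27 proliferation genes, 24 were detected (median 14.5 TPM), led by the replication genes Mcm3 (233 ± 84.1) and Pcna (227 ± 99.2), by Ccna2, which overlaps an opposite gene, and by Mcm6 (170 ± 68.5). Against 10000 random lists of coding genes of equal size, the median log2(TPM + 1) of the T cell, activation, glycolysis and oxidative phosphorylation lists stood at percentile 100, proliferation at 99.98, Treg at 97.1, Tfh at 97.9, Th1 at 85.2, Th2 at 69.3 and Th17 at 17.8. In all, 12 of 32 lists stood above percentile 95, a threshold chosen after the data were seen. Without replicate 2 there were 10, the Treg and Tfh lists no longer among them, and there were 4 with random lists drawn from coding genes with a mean TPM of at least 1. Against the latter, the T cell, glycolysis and oxidative phosphorylation lists stood at percentile 100, activation at 99.2, proliferation at 76.2, Tfh at 27.3, Treg at 16.04, and Th1, Th2 and Th17 at 0. In this setting the random lists held no gene under that mean, while the fixed lists kept their undetected members. Those were 10 of 27 genes in Th1, 9 of 20 in Th2 and 13 of 18 in Th17. Low percentiles of such lists therefore follow in part from the setting itself.

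Within the cytokine list of 42 genes, of which 18 were detected, Lta, Il2 and Tnf were followed by Tnfsf11 (72.5 TPM ± 29.2; SD, n = 3) and Ltb (60.3 ± 25.1). Of 33 cytokine receptor genes 21 were detected, with Il2ra, Il2rb (41.1 ± 13.8), Il21r, Il2rg and Il27ra the highest, all clear but Il27ra. Of 24 chemokine receptor genes 7 were detected, led by Ccr7, Gpr183 (63.7 ± 19.8), Ptger4, Ccr8 and Ccr4, of which Gpr183 and Ptger4 have an opposite gene. Of 40 helper transcription factor genes 27 were detected, led by Irf4, Tcf7, Foxp3, Junb (122 ± 12.9) and Ikzf1, of which Irf4 alone is clear.

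Counts were found for 16838 genes in replicate 1, 12527 in replicate 2 and 15976 in replicate 3, and 1912, 430 and 1888 genes had exactly 1 count. Pearson r of log2(TPM + 1) across genes was 0.950 between replicates 1 and 2, 0.967 between 1 and 3 and 0.938 between 2 and 3; genes are not independent replicates. As a check for a library deposited more than once, the chi-square statistic of the counts was 10.8, 23.2 and 17.9 times its degrees of freedom in those pairs, and no pair agreed within sampling noise. The edgeR biological coefficient of variation was 0.312 over 9466 genes and 0.241 over 5127 clear genes. Of 5314 coding genes with a mean TPM of at least 10, 139 had an SD of log2(TPM + 1) above 1, against 398 without replicate 1 and 218 without replicate 2. Over clear genes the number was 365 of 5299, where a mean of 10 in recomputed TPM is a looser cutoff. The median SD was 0.325 over those clear genes and 0.494 over the 5314. Of the 139, the 10 with the largest SD, among them Gm10337, Gm10972, Pcbd2 and Prelid2, had 0 counts in at least 1 library. Pcbd2 had 36, 0 and 12 counts and Prelid2 45, 0 and 12 in replicates 1, 2 and 3. Of the 10, 6 have at most 165 bases of exons. Of the list of 5 genes that holds Xist and Y-linked genes, 0 were detected in every library. Xist had 807, 1110 and 4 counts in replicates 1, 2 and 3, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 161, 133, 69 and 32 counts in replicate 1, 0 each in replicate 2, and 81, 68, 46 and 20 in replicate 3, although the replicates share a donor record. The spread between replicates includes these genes, and Eif2s3y and Ddx3y were among the 10 clear genes of largest SD. Cytokine genes also varied between libraries, with a median SD of log2(TPM + 1) of 0.68 against 0.44 for random lists matched on expression, at percentile 100 of these with all genes and with clear genes.

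**Figure D3:**
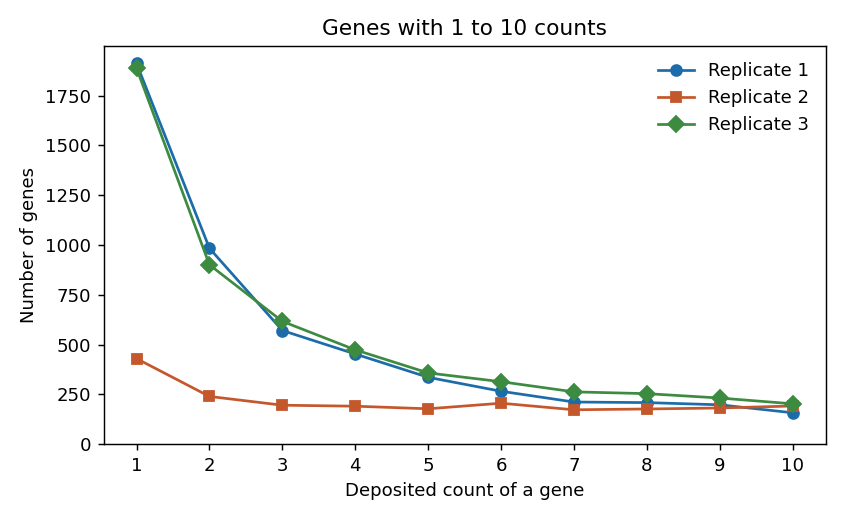
Number of genes (vertical axis) with each deposited count from 1 to 10 (horizontal axis), with a line per library. Replicate 2 had 430 genes at 1 count against 1912 and 1888 in replicates 1 and 3, while at 10 counts the libraries had 158, 192 and 203 genes in replicates 1, 2 and 3.

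By share of TPM, ribosomal protein genes made up 6.40% ± 1.76 (SD, n = 3), mitochondrial genes 4.47% ± 0.78, protein-coding genes in all 47.9% ± 7.12, genes annotated as antisense 27.8% ± 3.70 and the 10 highest genes 11.6% ± 2.06. Genes with opposite-strand exons held 71.8% ± 6.81 of TPM. If reads were counted on the opposite strand, the shares in this paragraph do not give the RNA composition of the cells, and the antisense share may not be antisense RNA. Genes annotated as rRNA held 1.30% ± 0.764, replication-dependent histone genes 0.00693% ± 0.00411 (0.00459% without replicate 2) and noncoding RNAs without a poly(A) tail 0.0023% ± 0.000659. The rRNA share came largely from CT010467.1 (12333 TPM ± 7647), which overlaps opposite-strand exons of Gm42418 by 1822 bases. CT010467.1 had 30179, 34666 and 80581 counts in replicates 1, 2 and 3, and Gm42418 had 1670, 1466 and 1785. Both genes were chosen after their values were seen. The mitochondrial share came largely from mt-Nd6 (19920 TPM ± 4342) and the tRNA gene mt-Tp (10595 ± 2048), chosen after their values were seen, while mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l had 0 counts in each library.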

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

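The T cell list stayed above the 9 other lists and past the threshold, and no helper comparison passed it, under every alternative run; posterior mean TPM was not run, since the tables used here hold counts. Tests over clear genes were chosen after the data were seen. Where a value moved, the cause was not tested unless the setting itself states it. With members at 1 TPM in any library the Th1 minus Tfh difference turned from -0.51 to 0.39, neither past the threshold. Coding genes at a TPM of 5 numbered 5753. The lowest correlation was 0.917 with a pseudocount of 0.1, 0.893 over coding genes with a mean TPM of at least 1, 0.862 as Spearman rho and 0.921 over clear genes, and 0.938 to 0.967 with a replicate left out. The coefficient of variation was 0.433 with no filter, 0.237 by DESeq2's median gene-wise dispersion, 0.241 over clear genes and 0.276 to 0.346 with a replicate left out. In CPM, which is not scaled by length, the log2 ratio of Tbx21 to Bcl6 was -2.39 and that of Ifng to Il21 was -2.27, against -0.25 in TPM and 0.41 in TPM without replicate 1, where the floor sets the values of 2 libraries. Variable genes numbered 281 at a mean TPM of 5, 91 with TMM scaling and 365 over clear genes, where the cutoff is looser. With a replicate left out they numbered 151 to 398, the highest without replicate 1. Lists above percentile 95 for level numbered 4 with random lists from coding genes with a mean TPM of at least 1, a filter not applied to the fixed lists. Lists above it for spread numbered 10, against 6 with TMM scaling, 2 over clear genes and 4 to 11 with a replicate left out, the lowest without replicate 3. As a share of counts, mitochondrial genes held 1.08%, replication-dependent histone genes 0.00192%, noncoding RNAs without a poly(A) tail 0.000385%, the 10 highest genes 4.03%, coding genes 75.1% and antisense genes 12.7%, since a share of counts is not scaled by length. For single genes and lists, 795 alternative values moved by less than 1 SD and 122 by more; the spread percentiles have no value per library, so their SD is that over the 3 left-out settings. Tbx21, Ifng and Il4 rest on few counts, and whether depth is what limits them was not tested. No paired analysis was possible because there is 1 group.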

Other observations

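Members of the proliferation list differed widely in level. The replication licensing genes Mcm3, Mcm6, Mcm4, Mcm5 and Mcm2 and the sliding clamp gene Pcna, all clear genes, had mean values from 73.9 to 233 TPM (n = 3 libraries). The mitotic genes Ccnb1 (1.65 TPM ± 1.21; SD, n = 3), Ccnb2 (0.467 ± 0.422), Aurkb (4.05 ± 3.07) and Birc5 (4.46 ± 2.27) are also clear. Apart from Mcm3, Mcm6 and Pcna, these genes were chosen after their values were seen, no such groups were fixed beforehand, and no difference between them was tested. Heat shock and immediate early genes were led by Hspa8 (1061 TPM ± 387) and Hsp90aa1 (633 ± 234), with 9 of 16 detected. Of 12 long noncoding RNAs 7 were detected, led by Gas5 (105 ± 39.8) and Malat1, which have opposite genes, and Mir155hg (49.4 ± 23.9), and 7 of 8 replication-independent histone genes were, led by H3f3b (138 ± 40.4). Of 12 noncoding RNAs without a poly(A) tail 1 was detected.

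For the patterns that follow, the tests of Tsix against Xist, of genes at 0 in replicate 2, of the overlapped share of coding genes and of histone levels beside Rn7sk, Rmrp and Rpph1 were set before their results were seen, and the other tests after; no biological explanation was tested, since there is 1 group. Many genes that overlap a gene of the other strand held high counts. A library that does not mark strand is argued against as the cause. It would give about equal values, and the highest median of coding over nested noncoding counts per kilobase was 5.33%. A candidate explanation is that a stranded library was counted on the strand opposite to transcription. The test set beforehand asked for at least 3 times as many Tsix as Xist counts in replicate 2. It gave 2.72, short of that limit, so this explanation stays open. The limit took no account of length, and 1943 of the 17923 exon bases of Xist overlap Tsix exons. Scaled by length, replicate 2 had 389 TPM for Tsix and 48.6 for Xist, a comparison made after the values were seen. Transcription of the opposite genes themselves stays open too: at least 83.3% of nested noncoding genes exceeded their coding partner and mt-Nd6 had at least 6.40 times the counts per kilobase of mt-Co1 in each library, past limits set only after the pattern was seen, but high counts on these genes are also what their own transcription would give. Across 2594 overlapping coding genes the Spearman rho of counts per kilobase with the overlapped share of exon length was at least 0.202, between the limits of 0.1 and 0.3 set beforehand. If reads were counted on the opposite strand, the levels of clear genes may come from a small remainder of reads that differs between libraries, and low counts of Ifng and Tbx21 may say little about their expression.

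Replicate 2 counted 12527 genes, against 16838 and 15976 in replicates 1 and 3. Lower depth is argued against: thinned to the total of replicate 2, the other libraries counted 15656 genes or more. A filter on low counts is argued against by 430 genes with exactly 1 count. Few distinct RNA molecules, each read several times, may be the cause: of clear genes placed by the other libraries at 2 to 5 counts, 65.1% were at 0 in replicate 2, against 24.3% and 12.04% in replicates 1 and 3. That is 2.68 times the higher of those, short of the 3 times set beforehand, so this stays open.

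The labels speak of total RNA and of a poly(A) protocol. The median replication-dependent histone gene had 0.0258 TPM, under the limit of 1 set beforehand for poly(A) selection. Over the clear ones the median was 0.996 in recomputed TPM, a larger scale for which that limit was not set. Counting on the opposite strand could also make these values low. Rn7sk and Rmrp were at 6.74 and 0.546 TPM, but Rpph1 at 13.99 TPM passed the limit of 10 set beforehand, so the kind of library cannot be told apart from these values. Histone reads may also have been lost because near-identical copies share them. The linker histones Hist1h1c and Hist1h1e, less alike, had means over the libraries of at most 3.25 TPM, and Hist1h1e had 6.29 TPM in replicate 2. These values rest on few counts and leave this open.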
